A study of Mus musculus with 2 samples.

How the data were processed

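Gingival CD11b+ cells from mice that received 10% Tet2-/- or 10% Tet2+/+ bone marrow transplantation (BMT) were measured by single-cell RNA sequencing, with 1 library per group. Per the labels, about 20000 cells per library were loaded with the Chromium Next GEM Single Cell 3' kit, version 3.1, and sequenced on a NovaSeq. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 6.1.2, while the header of the deposited matrices names Cell Ranger 4. The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, with empty barcodes included. They list 32285 genes, of which 32235 identifiers matched the GENCODE M21 annotation used for positions.

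Barcodes with at least 500 UMIs numbered 9844 in the 10% Tet2-/- BMT library and 12161 in the 10% Tet2+/+ BMT library. Of these, 248 and 489 had fewer than 250 genes or over 10% mitochondrial UMIs and were removed. Scrublet, as run in scanpy 1.11.5 with an assumed doublet share of 8%, marked 1 and 0 cells, which is too few for a caller that works, so doublets remain in the data. The 9595 and 11672 kept cells hold 85264406 and 87908757 UMIs.

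Counts of both libraries were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen by dispersion in 20 bins of expression, leaving out sex-linked, haemoglobin, mitochondrial and ribosomal genes. From 30 principal components of scaled values clipped at 10, the 20 nearest neighbours of each cell gave a shared-neighbour graph. Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, 5 iterations, seed 1) made 29 clusters. Each took the name of the best of 17 marker lists, such as S100a8, Retnlg and Csf3r for neutrophils, Camp, Ltf and Elane for immature neutrophils, Ly6c2, Ccr2 and Vcan for monocytes, C1qa, Apoe and Mrc1 for macrophages and Flt3, Cd209a and Ccr7 for dendritic cells. A name needed at least 3 markers detected in 10% or more of the cells with a log2 excess of 0.5 or more (pseudocount 20 CPM). A cluster stayed unnamed when its 10 leading genes held more markers of another list, when it was shallow without markers among them, or when 3 or more gland secretory transcripts led it. The marker lists were fixed first, while these thresholds and conditions for naming were set when the clusters were seen.

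UMIs were summed per library and class and scaled to CPM, the counts of a gene over the total of its class and library in the usual unit. Log2 ratios of 10% Tet2-/- over 10% Tet2+/+ BMT used a pseudocount of 10 CPM. Genes were eligible at 50 CPM or more in either library and 100 UMIs or more over both, and the size rule was 1.5-fold. With 1 library per group no test was possible. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact binomial (Clopper-Pearson) intervals, all at 95%. Intervals of list medians are not exact and hold the middle 95% of 500 Poisson redraws of the counts. For the ratio of relative Y-linked levels between classes, the bounds of the first level were divided by the opposite bounds of the second. The named genes are the 12 highest and 12 lowest past the size rule in each class, with Tet2, Il1b, Il6 and Tnf always named. Ribosomal, mitochondrial, haemoglobin, immunoglobulin, T cell receptor, Xist and Y-linked genes and models without a symbol were left out of that ranking and given as groups. Examples for the 36 gene lists are the members with the largest log2 ratio in either direction at 50 CPM or more, 2 to 4 as a rule and fewer where fewer reach that level. The median of each list, over members at 10 CPM or more, was set against 10000 random lists matched in 20 bins of expression.

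The groups, cell filter, marker lists, gene lists, size rule, rule for named genes and a first set of other settings were fixed before the data were examined. That set held other minimums of UMIs, genes and mitochondrial share, no doublet removal, clustering at resolutions 0.5 and 2, libraries clustered alone, median-of-ratios and TMM scaling (30% of ratios and 5% of levels trimmed), the mean of per-cell CPM, cells thinned to 500 UMIs, subtraction of free RNA profiled in barcodes with 1 to 50 UMIs, a pseudocount of 1 CPM and a minimum of 10 CPM. Settings chosen after seeing the data were removal of the 8% of cells with the highest doublet scores, free RNA profiled in barcodes with 51 to 200 UMIs, unnamed clusters whose best list was neutrophil added to that class, the cycling monocyte-like cluster left out, and Xist-carrying against Y-carrying cells. Cells were typed by sex from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty.

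The comparison was tested on simulated data, drawn as Poisson counts from a shared profile with no spread between animals or libraries. Shifts were given only to genes well above the eligible minimum, and unshifted lists held genes drawn independently. The simulation therefore checks the computation, not differences between animals or lists of genes that vary together. Of genes shifted by a log2 ratio of 0.8, 99% or more in each class passed the size rule in the right direction, and 0 unshifted genes passed it. Ratio intervals held the simulated ratio for 95.7%, 95.7% and 95% of genes in neutrophil-like, monocyte/macrophage-like and dendritic-like cells. Of 100 unshifted lists, 1, 4 and 4 lay beyond the outermost percentiles. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and Matplotlib 3.10.9.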

Results

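Gingival CD11b+ cells, the myeloid fraction of the gum, were profiled by single-cell RNA sequencing in mice that had received bone marrow transplantation (BMT) labelled 10% Tet2-/- or 10% Tet2+/+. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA. At 12 weeks after transplantation both groups had ligature-induced periodontitis, in which a thread around a tooth provokes gum inflammation, for 5 days. Each group had 1 library, so no difference could be set against the spread between animals, no test was made, and every statement describes these 2 libraries alone. Intervals cover counting error only. They are exact 95% intervals, apart from those of list medians and of the ratio of relative Y-linked levels between classes. A gene is called higher or lower in a count when its log2 ratio, with a pseudocount of 10 CPM (a gene's UMIs scaled by the total of its class and library), passes 1.5-fold, and between otherwise, while the printed folds carry no pseudocount and can therefore be larger. The sort differed per the labels: CD45.2+CD11b+ cells for 10% Tet2-/- BMT and CD45+CD11b+ cells for 10% Tet2+/+ BMT, although the sample title of the latter also names CD45.2+CD11b+.

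The 10% Tet2-/- BMT library held 93919724 UMIs and the 10% Tet2+/+ BMT library 100782700 UMIs. After the cell filter, 9595 and 11672 cells were kept. They carried a median of 5920 and 5009 UMIs and of 1553 and 1539 genes. The kept cells held 90.8% and 87.2% of all UMIs, and the median mitochondrial share per cell was 0.822% and 0.933%.

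Tet2 transcripts were not lower in the 10% Tet2-/- BMT library. Tet2 (ENSMUSG00000040943, chromosome 3 of mm10, 133463679 to 133545139, minus strand) was at 97.8 CPM (95.7 to 99.9) against 81.7 CPM (79.8 to 83.6) over all kept cells. The ratio was 1.2 (1.16 to 1.24), with 8337 and 7185 UMIs. By class, the ratio was 1.34 (1.27 to 1.42) in neutrophil-like cells, 1.24 (1.16 to 1.33) in monocyte-like cells, 1.2 (1.03 to 1.4) in dendritic-like cells and 0.95 (0.837 to 1.08) in macrophage-like cells. The deleted part of Tet2 is not given in the sources used here, and the 3' assay counts transcript ends, so a transcript that lost inner exons would still be counted and these values check nothing about the genotype. Nor does a file mark which cells descend from the 10% Tet2-/- marrow.

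Transcripts of the sex chromosomes set the libraries apart. Xist, the non-coding RNA of the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), was at 375 CPM in kept cells of the 10% Tet2-/- BMT library and 0.0796 CPM (7 UMIs) in those of the 10% Tet2+/+ BMT library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together were at 21 against 167 CPM. As a percent of the 10% Tet2+/+ BMT level, Y-linked transcripts were at 4.92% (4.15 to 5.8) in monocyte-like cells, 7.93% (7.09 to 8.85) in neutrophil-like cells, 9.14% (6.95 to 11.8) in dendritic-like cells and 38.1% (34.2 to 42.5) in macrophage-like cells. Genotype of the transplant and sex of most typed cells therefore differ between the libraries together, and by some of the labels so does the sort gate.

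**Figure D1:**
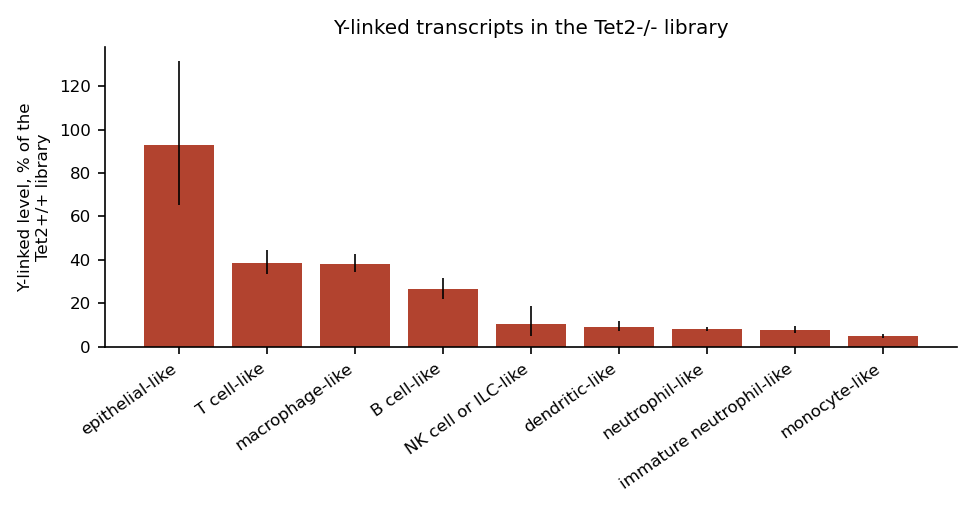
Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty together) in each plotted class of the 10% Tet2-/- BMT library, as a percent of the level in the same class of the 10% Tet2+/+ BMT library, with exact 95% intervals of counting error. Osteoclast-like and mast cell or basophil-like cells are not drawn. Monocyte-like cells are at 4.92%, macrophage-like cells at 38.1% and epithelial-like cells at 92.9%.

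The first question of the design is which myeloid cells the library of each group held. Monocyte/macrophage-like cells made up 20.2% (19.4 to 21) against 16.4% (15.8 to 17.1) of kept cells in 10% Tet2-/- against 10% Tet2+/+ BMT. Neutrophil-like cells were the most abundant class at 46.7% (45.7 to 47.7) against 44.4% (43.5 to 45.3), and immature neutrophil-like cells, which carry granule transcripts such as Camp and Ltf, were at 9.47% (8.89 to 10.1) against 6.43% (6 to 6.89). Dendritic-like cells were at 3.1% (2.76 to 3.46) against 2.36% (2.1 to 2.66). Within the monocyte/macrophage-like class, monocyte-like cells were at 12.8% (12.1 to 13.4) against 10.2% (9.62 to 10.7) and macrophage-like cells at 7.46% (6.94 to 8.01) against 6.28% (5.85 to 6.74). Osteoclast-like cells, of the bone-resorbing type, were at 0.365% (0.254 to 0.507) against 0.214% (0.139 to 0.316).

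Lymphoid cells, of which the CD11b gate should remove most B and T cells, were lower in 10% Tet2-/- BMT. B cell-like cells were at 3.38% (3.02 to 3.76) against 4.59% (4.22 to 4.99), T cell-like cells at 2.26% (1.97 to 2.58) against 2.9% (2.61 to 3.23) and NK cell or ILC-like cells at 0.667% (0.514 to 0.851) against 1.23% (1.04 to 1.45). Mast cell or basophil-like cells were at 0.104% (0.05 to 0.192) against 0.274% (0.188 to 0.387) and epithelial-like cells at 0.323% (0.22 to 0.458) against 0.343% (0.245 to 0.466). No cluster took the name of the eosinophil, plasma cell, fibroblast, endothelial, erythroid or platelet list. Clusters left unnamed held 13.4% (12.7 to 14.1) against 20.8% (20 to 21.5). Among them, a cluster led by Siglecf had 4.43% against 12.7% of kept cells. Its best list was neutrophil, with 11 markers of that list detected and S100a8 at 31914 against 34172 CPM. It stayed unnamed because Siglecf, of the eosinophil list, was the only marker of either list among its leading genes. Siglecf also belongs to the list of tissue-aged and activated neutrophil genes, so these cells are not shown to be eosinophils. A cluster led by Arg1 had 3.26% against 0.668%, a cluster of low depth (median 774 UMIs) led by immunoglobulin and haemoglobin transcripts 4.18% against 5.57%, and clusters led by Obp1a, Ccl8 and Hpgds 0.907% against 0.84%, 0.448% against 0.625% and 0.177% against 0.36%.

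The difference in the share of neutrophil-like cells was 2.28 points, but it was -6.11 points when the unnamed clusters whose best list was neutrophil were added and -1.1 points with a minimum of 1000 UMIs per cell. The epithelial-like cells differed in kind, with Bpifb9b at 38280 against 38.8 CPM and Cyp2a5 at 17.3 against 4321 CPM. Whether the sort gate, the tissue dissected or the recovery of cells contributed to the shares was not tested.

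**Figure D2:**
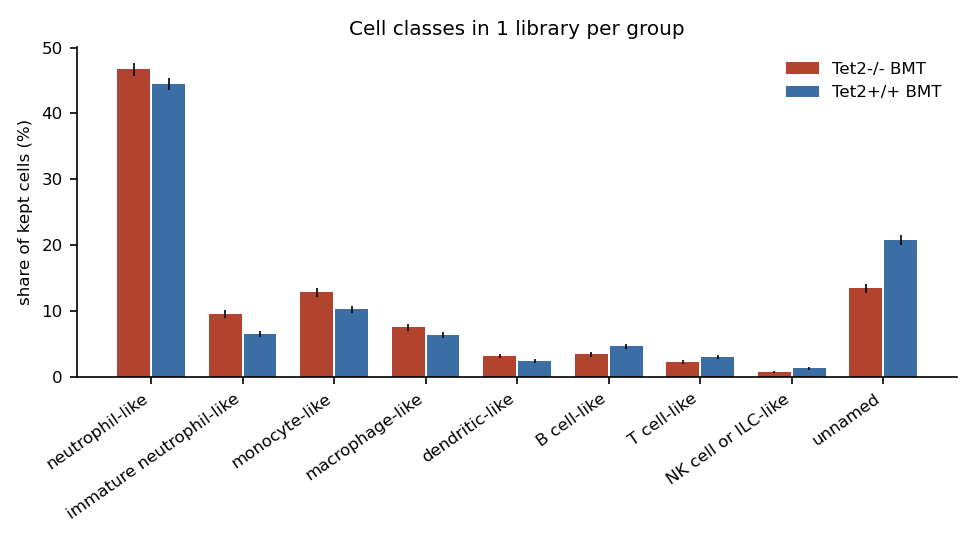
Share of kept cells (percent) in the larger classes and the unnamed clusters of the 10% Tet2-/- and 10% Tet2+/+ BMT libraries, with exact 95% binomial intervals that cover counting error only. Epithelial-like, osteoclast-like and mast cell or basophil-like cells are not drawn. Monocyte-like, macrophage-like, immature neutrophil-like and dendritic-like shares are higher in 10% Tet2-/- BMT, and unnamed clusters hold 13.4% against 20.8%.

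Neutrophil-like cells were compared to find which transcripts of the most abundant class differed between 10% Tet2-/- and 10% Tet2+/+ BMT. Transcripts induced by interferon were lower in 10% Tet2-/- BMT, and several chemokine and cytokine transcripts were higher. Ifit1, an interferon-induced RNA-binding protein (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), was at 31.6 against 98.9 CPM, 3.13-fold lower (95% interval 2.87 to 3.41). Spp1, which encodes the secreted protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was at 225 against 64.7 CPM, 3.48-fold higher (95% interval 3.29 to 3.68). Ccl4, a chemokine that attracts leukocytes (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), was at 1149 against 484 CPM, 2.37-fold higher (95% interval 2.32 to 2.42).

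Among the 23 measured interferon-stimulated genes, 14 were lower by 1.5-fold or more, 9 lay between and 0 were higher. Their median log2 ratio was -0.75, and besides Ifit1 examples are Oasl2 (2.94-fold lower, 2.79 to 3.1), Ifit3 (3.1-fold lower, 2.81 to 3.44) and Slfn5 (2.62-fold lower, 2.47 to 2.78). Interferon-gamma response and guanylate-binding genes had a median of -0.53, with 5 of 12 lower, 7 between and 0 higher, for example Cxcl10 (2.31-fold lower, 2.1 to 2.53) and Gbp2 (1.76-fold lower, 1.61 to 1.92). MHC class II presentation genes had a median of -0.29, with 1 of 9 lower, 8 between and 0 higher. Members were Ctss (1.94-fold lower, 1.82 to 2.06), Cd80 (1.46-fold higher, 1.38 to 1.55) and Cd74 (1.33-fold lower, 1.29 to 1.37). The median of that list was 0.51 after subtraction of free RNA profiled in barcodes with 1 to 50 UMIs. It was -0.38 with Xist-carrying cells of 10% Tet2-/- BMT against Y-carrying cells of 10% Tet2+/+ BMT, but 0.256 (0.125 to 0.389) with Y-carrying cells of both libraries. Most cells of the class lay in the clusters led by Retnlg, Csf3r and Cxcl2 in both libraries, with the cluster led by Cxcl2 the largest in 10% Tet2-/- BMT and that led by Csf3r the largest in 10% Tet2+/+ BMT. The cluster led by Ifit1 held more of the class in 10% Tet2+/+ BMT and the cluster led by Il1rn, with Spp1 and Rhov among its leading genes, more of it in 10% Tet2-/- BMT. Values of these genes over the class therefore hold both the mix of clusters and levels within them, which were not separated.

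Inflammatory cytokine genes had a median log2 ratio of 0.41, with 4 of 9 measured members higher, 5 between and 0 lower. Higher members were Ccl3 (2.06-fold higher, 2.01 to 2.12), Tnf (2.17-fold higher, 2.05 to 2.3), Csf1 (1.78-fold higher, 1.71 to 1.85) and Il1a (1.79-fold higher, 1.68 to 1.91). The ratio of Il1a depends on leaving out the unnamed cluster led by Siglecf, whose best list was neutrophil. Il1a was at 408 against 368.5 CPM there, with 845 and 2798 UMIs, but at 103.7 against 57.89 CPM in the class. Il1b, an abundant transcript here, was at 13361 against 11601 CPM, 1.15-fold higher (95% interval 1.15 to 1.16), and Il6 had 10 UMIs in each library. Tissue-aged and activated neutrophil genes had a median of 0.42, with 5 of 19 higher, 1 lower and 13 between, and include Spp1, Ccl3, Ccl4 and Csf1. NF-kB targets and feedback genes had a median of 0.32, with 1 of 17 higher, 16 between and 0 lower, for example Traf1 (1.8-fold higher, 1.68 to 1.93), Nfkbiz (1.5-fold higher, 1.47 to 1.52) and Nfkbia (1.45-fold higher, 1.43 to 1.46). CXC chemokines had a median of 0.07, with 1 of 4 higher, 1 lower and 2 between, and held Cxcl10 (2.31-fold lower, 2.1 to 2.53) and Cxcl2 (1.71-fold higher, 1.7 to 1.72). CC chemokines had a median of 0.15, with 2 of 6 higher, 1 lower and 3 between, and hold Ccl3 and Ccl4. When Xist-carrying cells of the 10% Tet2-/- BMT library were set against Y-carrying cells of the other library, the medians were 0.21 for cytokines, 0.12 for NF-kB targets, 0.04 for tissue-aged and activated genes and -0.01 for CC chemokines. The log2 ratio of Il1b was then -0.35. With Y-carrying cells of both libraries the medians of these lists were 0.78, 0.61, 0.93 and 0.44, so their height depended on which cells were compared. The Y-carrying cells of 10% Tet2-/- BMT lay more in the clusters led by Cxcl2 and by Il1rn, which hold activation genes, than those of 10% Tet2+/+ BMT, and this mix was not separated from levels within clusters. Of the 4482 neutrophil-like cells of 10% Tet2-/- BMT, 1048 carried Xist alone and 3239 neither marker. Xist was seen in 50.1% of those in the cluster led by Mmp8 but in 15.2% of those in the cluster led by Cxcl2. Xist-carrying cells thus were not a like sample of the class either.

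Immediate early and dissociation genes, which also respond to tissue handling, had a median of 0.24, or 0.00 with Xist-carrying against Y-carrying cells. Counts were 2 of 17 higher, 15 between and 0 lower, with Fosb (1.7-fold higher, 1.64 to 1.75), Egr3 (1.92-fold higher, 1.74 to 2.12) and Nr4a1 (1.43-fold higher, 1.4 to 1.47) as examples. Oxidative phosphorylation genes had a median of -0.21, with 19 of 19 between, such as Cox6c (1.29-fold lower, 1.24 to 1.35) and Atp5e (1.26-fold lower, 1.22 to 1.3). Haemoglobin transcripts were 4.07-fold higher (3.97 to 4.18) as a share of the class total. Ribosomal protein transcripts made up 2.8% against 3.15% and mitochondrial transcripts 0.495% against 0.572% of that total.

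The genes with the highest ratios, besides Spp1, Ccl3, Ccl4 and Tnf, were Rhov (3.61-fold, 3.27 to 3.98), Asprv1 (2.53-fold, 2.45 to 2.62), Tnfrsf23 (2.49-fold, 2.31 to 2.69) and Olr1 (2.29-fold, 2.09 to 2.51). The anti-apoptotic gene Bcl2a1b (1.93-fold, 1.85 to 2.02) followed, with Rgcc (2.02-fold, 1.9 to 2.14), Ifrd1 (1.93-fold, 1.86 to 1.99) and Rilpl2 (1.99-fold, 1.86 to 2.13). The lowest ratios, besides interferon-stimulated genes, included the cystatin-type protease inhibitors Stfa1 (2.92-fold, 2.78 to 3.06) and Cstdc5 (2.82-fold, 2.58 to 3.09). Also among the lowest were Steap4 (2.86-fold, 2.65 to 3.09), Plac8 (2.65-fold, 2.5 to 2.81) and Slfn4 (2.48-fold, 2.39 to 2.58), and Mmp25 (2.4-fold, 2.25 to 2.55), Cyb5r1 (2.53-fold, 2.3 to 2.77) and Oser1 (2.38-fold, 2.18 to 2.59).

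Median log2 ratios of other lists, with members past 1.5-fold, began with NADPH oxidase and oxidative stress at 0.12 (0 higher and 0 lower of 17), pattern recognition receptors at 0.09 (1 higher and 1 lower of 11), glycolysis at 0.07 (0 higher and 0 lower of 18), apoptosis and survival at 0.06 (2 higher and 1 lower of 14), neutrophil primary granule at 0.05 (0 higher and 0 lower of 5) and neutrophil secondary and tertiary granule at 0.05 (0 higher and 1 lower of 14). Next in order came hypoxia response at 0.02 (1 higher and 0 lower of 12), inflammasome and IL-1 pathway at 0.00 (1 higher and 0 lower of 12), matrix proteases and remodelling at 0.00 (1 higher and 1 lower of 12), osteoclast differentiation at -0.00 (0 higher and 0 lower of 5), unfolded protein response at -0.00 (0 higher and 1 lower of 9) and haematopoietic transcription factors at -0.02 (0 higher and 0 lower of 10). Close to 0 lay anti-inflammatory and checkpoint at -0.04 (1 higher and 0 lower of 13), G2/M phase at -0.05 (0 higher and 0 lower of 4), eicosanoid and leukotriene synthesis at -0.05 (0 higher and 0 lower of 8), DNA methylation and demethylation at -0.05 (0 higher and 0 lower of 9), alternative activation at -0.06 (0 higher and 0 lower of 4) and neutrophil maturation at -0.08 (1 higher and 0 lower of 15). Below 0 lay complement and Fc receptors at -0.08 (0 higher and 1 lower of 13), chemokine and chemoattractant receptors at -0.09 (0 higher and 1 lower of 9), lipid and phagocytosis macrophage genes at -0.10 (1 higher and 0 lower of 12), MHC class I presentation at -0.10 (2 higher and 0 lower of 13), integrins and adhesion at -0.11 (1 higher and 0 lower of 14) and heat shock genes at -0.15 (0 higher and 0 lower of 8). Fewer than 3 members of the tissue-resident macrophage genes and S phase lists were measured in this class. Of 34 lists with enough measured members, 7 lay above and 4 below the middle 95% of random lists matched on expression.

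In all, 55 genes were higher and 48 lower by 1.5-fold or more among 2162 eligible genes, which is 53.4% higher, from 4482 and 5186 cells with a median of 4090 and 4062 UMIs. With Xist-carrying against Y-carrying cells 143 genes were apart, and 55 of the 103, or 53.4%, were among them. The balance depended on the setting: 27 were higher and 116 lower (18.9% higher) with Xist-carrying against Y-carrying cells, and 53 higher and 153 lower (25.7% higher) with the unnamed neutrophil-best clusters added. With TMM scaling, 112 were higher and 28 lower, which is 80% higher, because the median log2 ratio of eligible genes moved from -0.05 to 0.10. As TMM applies one factor to all genes, list medians between -0.15 and 0 lie near or above 0 with it.

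Monocyte/macrophage-like cells were compared to find which transcripts differed in the cells that enter the gum as monocytes or reside there as macrophages. Primary granule and G2/M phase transcripts were higher over the class in 10% Tet2-/- BMT, which went with a cluster of cycling cells, and several interferon-stimulated and heat shock transcripts were lower. Saa3, an acute-phase serum amyloid (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was at 125 against 8.91 CPM, 14.1-fold higher (95% interval 12.3 to 16.2). Elane, the elastase of primary granules (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), was at 182 against 65.1 CPM, 2.8-fold higher (95% interval 2.65 to 2.96). Chil1, a chitinase-like secreted protein (ENSMUSG00000064246, chromosome 1, 134182176 to 134190181), was at 25 against 98.1 CPM, 3.92-fold lower (95% interval 3.61 to 4.28).

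Primary granule genes had a median log2 ratio of 0.92, with 5 of 8 measured members higher, 3 between and 0 lower. Besides Elane these include Ctsg (2.9-fold higher, 2.66 to 3.16) and Prtn3 (2.44-fold higher, 2.35 to 2.53). G2/M phase genes had a median of 0.61, with 11 of 18 higher, 7 between and 0 lower, for example Cenpf (2.16-fold higher, 1.99 to 2.34), Mki67 (1.88-fold higher, 1.8 to 1.96) and Ube2c (1.84-fold higher, 1.74 to 1.94). S phase genes had a median of 0.44, with 1 of 17 higher, 16 between and 0 lower, such as Tyms (1.78-fold higher, 1.63 to 1.95) and Rrm2 (1.63-fold higher, 1.5 to 1.77). Without the monocyte-like cluster led by cycling genes, 53 genes were 1.5-fold apart, 39 of them among the 74 found with it. The medians were then 0.21 for primary granule, 0.09 for G2/M phase and 0.11 for S phase genes, and the log2 ratios of Elane and Ctsg 0.01 and -0.00. The higher values of these lists, and of Elane and Ctsg, thus went mostly with the cells of that cluster.

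Interferon-stimulated genes had a median of -0.41, with 6 of 25 lower, 19 between and 0 higher, for example Slfn4 (2.67-fold lower, 2.43 to 2.93), Slfn1 (1.93-fold lower, 1.83 to 2.04), Oasl2 (1.96-fold lower, 1.83 to 2.1) and Irf7 (1.66-fold lower, 1.58 to 1.74). Heat shock genes had a median of -0.29, with 2 of 11 lower, 9 between and 0 higher, and Hspa1a (2.37-fold lower, 2.23 to 2.52) and Dnajb1 (1.42-fold lower, 1.31 to 1.53) as examples. Immediate early and dissociation genes had a median of -0.12 with 17 of 17 between, such as Dusp1 (1.38-fold lower, 1.36 to 1.4) and Klf2 (1.26-fold lower, 1.24 to 1.28). That list was at 0.04 when cells were thinned to 500 UMIs. MHC class II presentation genes had a median of -0.20, or -0.01 without the cycling cluster, with 13 of 13 between, such as Ciita (1.31-fold lower, 1.21 to 1.42) and Cd74 (1.25-fold lower, 1.24 to 1.26). MHC class I presentation genes had a median of -0.13 with 14 of 14 between, such as H2-T23 (1.38-fold lower, 1.33 to 1.43) and H2-D1 (1.19-fold lower, 1.18 to 1.21).

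Tissue-resident macrophage genes had a median of 0.27, with 1 of 13 higher, 1 lower and 11 between, for example Pf4 (1.8-fold higher, 1.72 to 1.88), Stab1 (1.4-fold higher, 1.29 to 1.51) and F13a1 (1.3-fold higher, 1.26 to 1.33). The median was -0.32 with Xist-carrying against Y-carrying cells. Alternative activation genes had a median of 0.24, or -0.05 with Xist-carrying against Y-carrying cells. Of 10 members, 1 was higher, 1 lower and 8 between, for example Chil3 (2.27-fold higher, 2.23 to 2.31) and Retnla (1.5-fold lower, 1.45 to 1.55). Lipid and phagocytosis macrophage genes had a median of 0.08, with 2 of 18 higher, 0 lower and 16 between, for example Fabp5 (1.88-fold higher, 1.8 to 1.96) and Ctsd (1.37-fold higher, 1.34 to 1.4). Spp1, of the same list, was at 50.4 against 23.8 CPM, 2.12-fold higher (95% interval 1.92 to 2.34), but its log2 ratio was -1.44 after subtraction of free RNA profiled in barcodes with 51 to 200 UMIs. Inflammatory cytokine genes had a median of 0.08, with 1 of 10 higher, 9 between and 0 lower. Il6 was at 15.2 against 5.68 CPM, 2.67-fold higher (95% interval 2.2 to 3.26), Il1b at 2795 against 3034 CPM, 1.09-fold lower (95% interval 1.07 to 1.1) and Tnf at 60.7 against 56.8 CPM, 1.07-fold higher (95% interval 0.995 to 1.15). These values leave out the unnamed cluster led by Arg1, and no setting was made to add it. There Il6 was at 92.1 against 45.4 CPM (332 and 45 UMIs) and Spp1 at 3268 against 2557 CPM (11779 and 2533 UMIs). Saa3 went the other way there, at 745 against 1085 CPM. Whether the cells of that cluster belong to this class was not tested.

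Transcripts typical of neutrophils were also counted in this class. Secondary and tertiary granule genes had a median of -0.06, with 1 of 15 higher, 2 lower and 12 between, such as Chil3 (2.27-fold higher, 2.23 to 2.31) and Camp (1.64-fold lower, 1.61 to 1.67). Neutrophil maturation genes had a median of -0.16, with 1 of 14 lower and 13 between, such as Cxcr2 (1.8-fold lower, 1.7 to 1.9) and Stfa2l1 (1.34-fold higher, 1.26 to 1.43), and were at 0.35 after subtraction of free RNA profiled in barcodes with 1 to 50 UMIs. Haemoglobin transcripts were 22.5-fold higher (20.4 to 24.8) as a share of the class total.

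Other genes with the highest ratios were Fcnb (2.97-fold, 2.69 to 3.27) and Ifitm1 (2.11-fold, 2.05 to 2.18). The lowest ratios, besides Chil1 and genes already given, were Lyz1 (3.94-fold, 3.52 to 4.41), Cd177 (2.29-fold, 2.13 to 2.46), Gdpd3 (2.25-fold, 2.05 to 2.47) and Krt80 (2.07-fold, 1.92 to 2.23), and Ly6a (2.02-fold, 1.9 to 2.14), Eps8 (1.96-fold, 1.82 to 2.12) and Ace (1.85-fold, 1.74 to 1.98). Ace, which encodes angiotensin-converting enzyme, marks non-classical monocytes.

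The other lists, given in the same way, began with CXC chemokines at 0.17 (0 higher and 0 lower of 6), oxidative phosphorylation at 0.11 (0 higher and 0 lower of 19), glycolysis at 0.08 (0 higher and 0 lower of 18), tissue-aged and activated neutrophil at 0.08 (1 higher and 1 lower of 19), NADPH oxidase and oxidative stress at 0.07 (0 higher and 0 lower of 18) and chemokine and chemoattractant receptors at 0.07 (0 higher and 1 lower of 10). Lower medians were those of NF-kB targets and feedback at 0.05 (0 higher and 0 lower of 18), DNA methylation and demethylation at 0.04 (0 higher and 0 lower of 12), eicosanoid and leukotriene synthesis at 0.03 (0 higher and 1 lower of 12), hypoxia response at -0.01 (0 higher and 0 lower of 12), CC chemokines at -0.01 (0 higher and 1 lower of 11) and interferon-gamma response and guanylate-binding at -0.03 (0 higher and 0 lower of 15). Near 0 were anti-inflammatory and checkpoint at -0.03 (0 higher and 1 lower of 14), inflammasome and IL-1 pathway at -0.04 (0 higher and 0 lower of 12), pattern recognition receptors at -0.05 (0 higher and 0 lower of 13), matrix proteases and remodelling at -0.05 (1 higher and 0 lower of 16), apoptosis and survival at -0.05 (0 higher and 0 lower of 16) and integrins and adhesion at -0.09 (0 higher and 1 lower of 15). The lowest of these were unfolded protein response at -0.10 (0 higher and 0 lower of 10), osteoclast differentiation at -0.11 (0 higher and 0 lower of 7), haematopoietic transcription factors at -0.12 (0 higher and 0 lower of 12) and complement and Fc receptors at -0.12 (1 higher and 1 lower of 15). The median of CXC chemokines was -0.34 with Xist-carrying against Y-carrying cells and -0.01 with a mitochondrial limit of 5%. Of 36 lists with enough measured members, 6 lay above and 10 below the middle 95% of random lists matched on expression.

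In all, 43 genes were higher and 31 lower by 1.5-fold or more among 2934 eligible genes, from 1940 and 1919 cells with a median of 12544 and 11645 UMIs. The cluster led by Fn1 and that led by Retnla and Ccl7 were the largest of the class in 10% Tet2-/- and in 10% Tet2+/+ BMT. The cycling cluster, led by Pclaf, Mki67 and Top2a, held more of the class in 10% Tet2-/- BMT, and the clusters led by Apoc2, by Ace and by Ccl12 more of it in 10% Tet2+/+ BMT.

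Dendritic-like cells were compared to find which transcripts differed in cells specialised in antigen presentation. The chemokine transcripts Cxcl10, Cxcl9 and Ccl22 were higher in 10% Tet2-/- BMT, while a few heat shock and interferon-stimulated genes were lower. Cxcl10, a ligand of the chemokine receptor Cxcr3 of T cells (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), was at 123 against 43 CPM, 2.87-fold higher (95% interval 2.44 to 3.37). Ccl22, a ligand of Ccr4 on T cells (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699), was at 55.4 against 13.5 CPM, 4.11-fold higher (95% interval 3.12 to 5.48). Retnla, a secreted protein of alternatively activated macrophages, was at 115 against 7.28 CPM, 15.8-fold higher (95% interval 11.2 to 23).

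CXC chemokines had a median log2 ratio of 0.77, with 3 of 5 measured members higher, 2 between and 0 lower, for example Cxcl9 (1.76-fold higher, 1.59 to 1.96) and Cxcl2 (1.25-fold higher, 1.21 to 1.31), with Cxcl10 above. CC chemokines had a median of 0.24, with 3 of 11 higher, 8 between and 0 lower, for example Ccl5 (2.63-fold higher, 2.26 to 3.07) and Ccl17 (1.56-fold higher, 1.48 to 1.65). That median was below 0 in 6 other settings, from -0.17 without the 8% of cells with the highest doublet scores to -0.01 when cells were thinned to 500 UMIs. The log2 ratio of Ccl5 was 1.23, but below 0 in 4 settings, among them -0.35 without doublet removal and -0.61 with a mitochondrial limit of 5%. Interferon-gamma response and guanylate-binding genes had a median of 0.16, with 4 of 16 higher, 12 between and 0 lower, among them Gbp2 (1.63-fold higher, 1.34 to 1.99) and Ciita (1.23-fold higher, 1.12 to 1.34). Inflammatory cytokine genes had a median of 0.24, with 1 of 10 higher, 9 between and 0 lower, for example Osm (1.31-fold higher, 1.16 to 1.48) and Ccl3 (1.24-fold higher, 1.15 to 1.34). That median was -0.01 when cells were thinned to 500 UMIs. Il1b was at 3684 against 2917 CPM, 1.26-fold higher (95% interval 1.24 to 1.29) and Tnf at 66.7 against 62.7 CPM, 1.06-fold higher (95% interval 0.908 to 1.24), and Il6 had 22 and 14 UMIs.

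Interferon-stimulated genes had a median of -0.26, with 3 of 24 lower, 21 between and 0 higher, such as Slfn1 (1.9-fold lower, 1.57 to 2.3), Irf7 (1.57-fold lower, 1.39 to 1.76) and Xaf1 (1.6-fold lower, 1.32 to 1.94). Heat shock genes had a median of -0.27, with 2 of 10 lower, 8 between and 0 higher, such as Hspa1a (2.17-fold lower, 1.86 to 2.53) and Dnaja1 (1.35-fold lower, 1.25 to 1.46). S phase genes had a median of 0.38, with 4 of 15 higher, 11 between and 0 lower, such as Pcna (1.26-fold higher, 1.08 to 1.47). Alternative activation genes had a median of 0.09, with 3 of 9 higher, 6 between and 0 lower, and hold Retnla, Ccl22 and Ccl17. Complement and Fc receptor genes had a median of -0.12, with 1 of 16 lower, 15 between and 0 higher, such as Fcgr1 (1.78-fold lower, 1.47 to 2.17) and Fcgr2b (1.44-fold lower, 1.3 to 1.59).

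Transcripts typical of other cell types differed in this class too. Jchain, the joining chain of secreted antibodies, was at 138 against 3.43 CPM, 40.2-fold higher (95% interval 24.6 to 70.7), and its log2 ratio was 3.46, or -0.38 without the 8% of cells with the highest doublet scores. Immunoglobulin and T cell receptor transcripts together were 3.77-fold higher (3.65 to 3.89). Neutrophil transcripts were lower: S100a8 (1.61-fold, 1.58 to 1.64), Cxcr2 (1.98-fold, 1.67 to 2.34) and Hdc (1.86-fold, 1.63 to 2.12). Secondary and tertiary granule genes had a median of -0.27 with 14 of 14 between, and neutrophil maturation genes a median of -0.19 with 2 of 14 lower and 12 between, for example Csf3r (1.7-fold lower, 1.48 to 1.95) and Wfdc21 (1.45-fold lower, 1.3 to 1.62). After subtraction of free RNA profiled in barcodes with 1 to 50 UMIs, the log2 ratio of S100a8 was 0.27, and the medians were 0.07 and 0.23.

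Further high ratios were Ifitm1 (2.32-fold, 2.21 to 2.43), Grasp (2.21-fold, 1.89 to 2.59), Cd274 (2.07-fold, 1.66 to 2.61) and Stmn1 (2.02-fold, 1.65 to 2.47), and Acod1 (1.87-fold, 1.57 to 2.23) and Ncoa7 (1.87-fold, 1.6 to 2.19). Cd274 encodes the checkpoint ligand PD-L1 and Acod1 the enzyme that makes itaconate. Low ratios were Hmox1 (3.8-fold, 2.94 to 4.96), Spp1 (3.14-fold, 2.61 to 3.79), Tppp3 (2.99-fold, 2.47 to 3.62) and Krt80 (2.39-fold, 1.92 to 2.98), with Nupr1 (2.08-fold, 1.74 to 2.49), Oser1 (2-fold, 1.62 to 2.46) and Rsrp1 (1.7-fold, 1.52 to 1.9). Hmox1, which breaks down haem, had a log2 ratio of -1.41, or 0.33 with a minimum of 1000 UMIs per cell. That of Krt80 was -0.98, or 0.35 when cells were thinned. Tissue-aged and activated neutrophil genes, a list that holds Spp1 and Cd274, had a median of 0.03, with 1 of 17 higher and 1 lower. NADPH oxidase and oxidative stress genes, which include Hmox1, had a median of -0.07, with 0 of 17 higher and 1 lower.

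Among the remaining lists, the upper medians were those of NF-kB targets and feedback at 0.09 (0 higher and 0 lower of 18), DNA methylation and demethylation at 0.09 (1 higher and 0 lower of 12), MHC class II presentation at 0.07 (0 higher and 0 lower of 13), inflammasome and IL-1 pathway at 0.04 (0 higher and 0 lower of 13), neutrophil primary granule at 0.03 (0 higher and 0 lower of 3) and G2/M phase at -0.00 (3 higher and 0 lower of 7). They were followed by glycolysis at -0.01 (0 higher and 0 lower of 18), apoptosis and survival at -0.03 (0 higher and 0 lower of 16), tissue-resident macrophage genes at -0.04 (1 higher and 0 lower of 8), MHC class I presentation at -0.06 (0 higher and 0 lower of 14), oxidative phosphorylation at -0.06 (0 higher and 0 lower of 19) and immediate early and dissociation genes at -0.07 (0 higher and 0 lower of 17). Further down lay integrins and adhesion at -0.08 (0 higher and 0 lower of 16), unfolded protein response at -0.08 (0 higher and 0 lower of 10), anti-inflammatory and checkpoint at -0.08 (1 higher and 0 lower of 14), eicosanoid and leukotriene synthesis at -0.10 (0 higher and 0 lower of 10), chemokine and chemoattractant receptors at -0.11 (0 higher and 1 lower of 11) and lipid and phagocytosis macrophage genes at -0.11 (1 higher and 1 lower of 16). At the low end lay hypoxia response at -0.12 (0 higher and 1 lower of 11), matrix proteases and remodelling at -0.12 (0 higher and 0 lower of 14), haematopoietic transcription factors at -0.17 (0 higher and 1 lower of 13), pattern recognition receptors at -0.19 (0 higher and 0 lower of 10) and osteoclast differentiation at -0.20 (0 higher and 0 lower of 7). Of 36 lists with enough measured members, 6 lay above and 10 below the middle 95% of random lists matched on expression.

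In all, 22 genes were higher and 23 lower by 1.5-fold or more among 2691 eligible genes, from 297 and 276 cells with a median of 16944 and 15495 UMIs. The class was small, and 28 of these 45 genes were also found without the 8% of cells with the highest doublet scores.

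**Figure D3:**
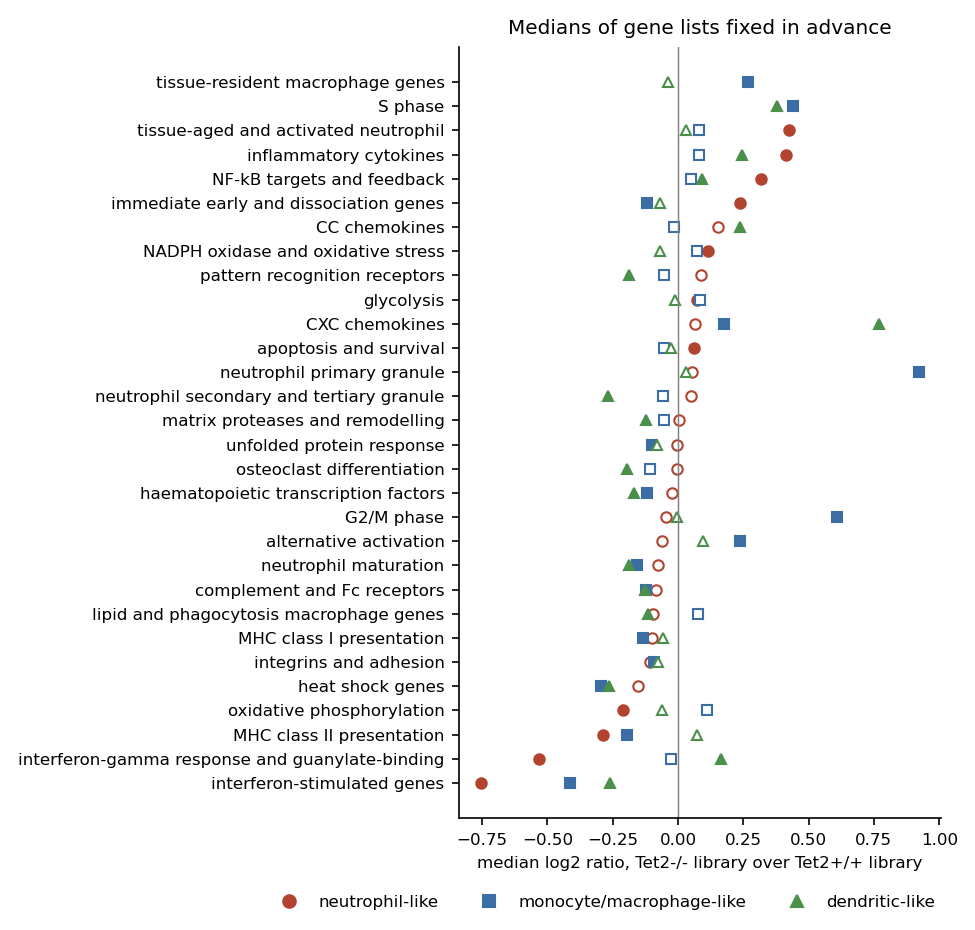
Median log2 ratio (10% Tet2-/- over 10% Tet2+/+ BMT) of fixed gene lists in 3 classes, with filled markers for lists among the most extreme 5% of random lists matched on expression. Lists that were not among that 5% in any of the 3 classes are not drawn. Interferon-stimulated genes lie below 0 in all 3 classes, at -0.75, -0.41 and -0.26.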

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

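The tests in this part were chosen only after the result was seen, apart from that of the depth of T cell-like cells, whose monocyte-like control was added afterwards.

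A signal outside the gene comparisons was Xist, with 31990 UMIs in kept cells of the 10% Tet2-/- BMT library against 7 in the other, while 553 cells of the former carried Y-linked transcripts without Xist. Free RNA from male cells would give every class a like Y-linked level, but in that library macrophage-like cells had 7.91 times (6.58 to 9.56) the level of monocyte-like cells, which argues against it as the whole cause. Marrow donors of both sexes that gave alike to each class are argued against by a ratio of 7.75 (5.9 to 10.2) between these classes when each is taken relative to the 10% Tet2+/+ BMT library. A candidate explanation that the values go with is a male recipient beside female donors, since 94.7% (74 to 99.9) of 19 typed epithelial-like cells, a type that marrow does not form, carried Y-linked transcripts without Xist. Sexes are not given in the sources used here, donors of both sexes that gave unequally to the classes stay open, and no biological explanation was tested.

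A further signal was that 308 cells of the 10% Tet2-/- BMT library carried both Xist and a Y-linked UMI, most often among T cell-like cells, which the CD11b gate should remove. Of Xist-carrying T cell-like cells 42.9% (35.1 to 50.9) had a Y-linked UMI, which is 12.6 times the 3.41% (2.44 to 4.64) in monocyte-like cells and argues against free RNA alone, which would give a like share. Doublets of cells of both sexes could give deeper cells, and T cell-like cells with both had 1.59 times the higher of the median UMIs of cells with Xist alone and with Y-linked transcripts alone. Monocyte-like cells with both were also deeper, at 1.34 times in the same measure. A deeper cell can show both more often, and whether these control cells hold doublets too was not tested. Doublets and depth therefore cannot be told apart by this measure. Cells with Xist alone had a median of 12208 UMIs in T cell-like and 13552 UMIs in monocyte-like cells. This argues against depth as the source of the difference in share between these classes. No biological explanation was tested.

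The unnamed cluster led by Arg1 held 3.26% of kept cells of the 10% Tet2-/- BMT library and 0.668% of those of the 10% Tet2+/+ BMT library, a signal outside the named classes.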

How the results depend on the processing

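The tests with Xist-carrying against Y-carrying cells, without the 8% of cells with the highest doublet scores, with free RNA from barcodes with 51 to 200 UMIs, with unnamed neutrophil-best clusters and without the cycling cluster were chosen only after the results were seen. No paired analysis was possible because each group has 1 library. Unless the construction shows it, the cause was not tested. The Tet2 ratio lay between 1.19 and 1.22 over 5 alternatives. Of the counts of genes 1.5-fold apart, 35 stayed within 1.5 times and 9 did not, with ranges of 99 to 206 in neutrophil-like, 51 to 129 in monocyte/macrophage-like and 45 to 1083 in dendritic-like cells. Of named genes, 484 values lay within the interval of the main ratio, 639 outside it and 11 reversed, where reversal was counted only for genes past 1.5-fold. The values carry the pseudocount and the interval does not, so a value can lie outside with no change of setting. The number outside therefore does not measure dependence on the processing. Il1b in neutrophil-like cells, an abundant transcript, went from 0.20 to -0.35 with Xist-carrying against Y-carrying cells. Of the medians of lists other than the leading 3, 338 stayed, 172 moved and 34 reversed. Log2 ratios and medians are given below as plain values, and differences in shares in points. The dendritic-like class rests on 297 and 276 cells.

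With a minimum of 1000 UMIs, the median of inflammatory cytokines in neutrophil-like cells was 0.37 and that of interferon-stimulated genes in monocyte/macrophage-like cells -0.49. The difference in neutrophil-like share reversed to -1.1, and the following reversed in dendritic-like cells: Hmox1 to 0.33, CC chemokines to -0.04, lipid and phagocytosis genes to 0.06 and pattern recognition receptors to 0.02. Neutrophil maturation genes in monocyte/macrophage-like cells reversed to 0.17. With 300 UMIs and 150 genes, Ccl5 (-0.10), CC chemokines (-0.10) and lipid and phagocytosis genes (0.03) reversed in dendritic-like cells, and neutrophil maturation (0.12) in monocyte/macrophage-like cells. With 5% mitochondrial UMIs, 74 genes were apart in dendritic-like cells, where Ccl5 (-0.61), Hmox1 (0.25), CC chemokines (-0.11), neutrophil maturation (0.09) and pattern recognition receptors (0.09) reversed, as did CXC chemokines in monocyte/macrophage-like cells (-0.01).

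Without doublet removal, which differs by 1 cell, Ccl5 in dendritic-like cells was at -0.35 after clustering anew. Without the 8% of cells with the highest doublet scores, 71 genes were apart in dendritic-like cells and interferon-stimulated genes in monocyte/macrophage-like cells were at -0.47. In dendritic-like cells Ccl5 (-0.53), Jchain (-0.38), CC chemokines (-0.17), complement and Fc receptors (0.07), lipid and phagocytosis genes (0.02), matrix proteases (0.13) and pattern recognition receptors (0.05) reversed, and neutrophil maturation (0.04) in monocyte/macrophage-like cells.

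A minimum of 10 CPM makes more genes eligible, and 185, 129 and 96 were apart in neutrophil-like, monocyte/macrophage-like and dendritic-like cells. With TMM, cytokines were at 0.57 and interferon-stimulated genes at -0.61 in neutrophil-like cells. With a pseudocount of 1 CPM, which shrinks ratios less, cytokines were at 0.77 and interferon-stimulated genes at -0.92 there and at -0.50 in monocyte/macrophage-like cells. With the mean of per-cell CPM, cytokines in neutrophil-like cells were at 0.39 and interferon-stimulated genes in monocyte/macrophage-like cells at -0.32. With cells thinned to 500 UMIs, which leaves few UMIs per gene, 1083 genes were apart in dendritic-like and 124 in monocyte/macrophage-like cells, cytokines in neutrophil-like cells were at 0.38 and interferon-stimulated genes in monocyte/macrophage-like cells at -0.29. Krt80 (0.35), CC chemokines (-0.01), cytokines (-0.01) and osteoclast differentiation (0.77) reversed in dendritic-like cells and immediate early genes (0.04) in monocyte/macrophage-like cells.

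With free RNA from barcodes with 1 to 50 UMIs subtracted, S100a8 (0.27), matrix proteases (0.01), neutrophil maturation (0.23), secondary granule (0.07) and pattern recognition (0.13) reversed in dendritic-like cells, MHC class II presentation (0.51) in neutrophil-like cells and neutrophil maturation (0.35) in monocyte/macrophage-like cells. With barcodes of 51 to 200 UMIs, Spp1 in monocyte/macrophage-like cells reversed to -1.44. With libraries clustered alone, differences in shares were 7.77 for neutrophil-like, 1.46 for monocyte/macrophage-like and 1.55 for dendritic-like cells. This setting and resolutions 0.5 and 2 were run for shares only, so gene and list values were not computed with them. With unnamed neutrophil-best clusters added, 206 genes were apart, cytokines were at 0.36 and interferon-stimulated genes at -0.62, and the neutrophil-like share (-6.11) and apoptosis and survival (-0.15) reversed.

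With Xist-carrying against Y-carrying cells, 73 genes were apart in dendritic-like cells, cytokines in neutrophil-like cells were at 0.21, and interferon-stimulated genes were at -0.91 there and at -0.52 in monocyte/macrophage-like cells. CC chemokines in dendritic-like cells (-0.06), apoptosis and survival in neutrophil-like cells (-0.01), and CXC chemokines (-0.34), alternative activation (-0.05) and tissue-resident macrophage genes (-0.32) in monocyte/macrophage-like cells reversed. Without the cycling cluster, interferon-stimulated genes in monocyte/macrophage-like cells were at -0.30, and Ctsg (-0.00) and immediate early genes (0.00) reversed.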

Other observations

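Immature neutrophil-like cells and the parts of the monocyte/macrophage-like class were compared in the same way, at the settings of the report alone. The tests of the lower interferon-stimulated genes were chosen only after the result was seen, apart from that with TMM scaling.

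Immature neutrophil-like cells, which lead with granule genes, had some higher chemokine transcripts in 10% Tet2-/- BMT, while secondary and tertiary granule genes had a median log2 ratio of -0.12. CXC chemokines there had a median of 0.87, with 2 of 3 higher, among them Cxcl2 (1.87-fold, 1.84 to 1.9) and Cxcl3 (2.06-fold, 1.85 to 2.31). Acod1, the enzyme that makes itaconate, was at 307 against 114 CPM, 2.7-fold higher (95% interval 2.54 to 2.86). The genes with the lowest ratios were Olfm4 (4.31-fold, 3.9 to 4.77), Ctse (4.52-fold, 3.88 to 5.28) and Mmp25 (2.55-fold, 2.33 to 2.79), followed by Slfn4 (2.11-fold, 1.95 to 2.29) and Hp (1.79-fold, 1.75 to 1.83), of which Hp encodes the haemoglobin-binding protein haptoglobin. Cstdc5 was 4.46-fold higher (3.85 to 5.18) here, but 2.82-fold lower (2.58 to 3.09) in neutrophil-like cells, and that difference was not tested. Interferon-stimulated genes had a median of -0.07 in immature cells, with 1 of 16 lower, 15 between and 0 higher, and Isg15 was at 76.8 against 52.1 CPM, 1.48-fold higher (95% interval 1.34 to 1.62). Other lists also had medians above 0, at 0.42 (with 3 of 16 higher) for immediate early and dissociation genes, which respond to handling, 0.53 (with 5 of 18 higher) for G2/M phase and 0.56 (with 4 of 8 higher) for MHC class II presentation genes. The cluster led by Ltf and Camp with Ngp held more of the class in 10% Tet2+/+ BMT, and those led by Elane and by Ltf with Cstdc5 more of it in 10% Tet2-/- BMT, so these values hold the mix of clusters too. In all, 75 genes were higher and 6 lower of 2129 eligible, around a median log2 ratio of all eligible genes of 0.14, from 909 and 751 cells.

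Monocyte-like and macrophage-like cells both had medians of interferon-stimulated genes below 0, at -0.41 and -0.48, and differed elsewhere. In monocyte-like cells, MHC class II presentation genes had a median of -0.38 with 4 of 13 lower, and Saa3 was at 174 against 11.2 CPM, 15.5-fold higher (95% interval 13.4 to 18.1). G2/M and S phase genes there had medians of 0.62 and 0.49, and the cycling cluster held more of the class in 10% Tet2-/- BMT. In the joint monocyte/macrophage-like class, the median of MHC class II presentation was -0.20, or -0.01 without that cluster, so the lower value in monocyte-like cells is not shown to be a change within clusters. In macrophage-like cells the genes lowest in 10% Tet2-/- BMT included the monocyte marker Ly6c2 (3.66-fold, 3.43 to 3.91), with Fn1 (4.35-fold, 4.04 to 4.68), Lyz1 (3.35-fold, 2.93 to 3.83) and Crip1 (2.2-fold, 2.13 to 2.26). Genes of resident macrophages had a list median of 0.28 there, with 3 of 16 higher, 1 lower and 12 between, and examples of Pf4 (1.8-fold higher, 1.72 to 1.88), Gas6 (1.74-fold higher, 1.54 to 1.98) and Igf1 (1.69-fold higher, 1.48 to 1.94). The median was 0.52 with Y-carrying cells of both libraries but -0.04 with Xist-carrying cells of the 10% Tet2-/- BMT library against Y-carrying cells of the other, so it depended on which cells were compared. In all, 55 genes were higher and 40 lower of 2976 in monocyte-like cells, and 20 higher and 41 lower of 2769 in macrophage-like cells. Haemoglobin transcripts were 56.9-fold higher (49 to 66.5) in macrophage-like cells of 10% Tet2-/- BMT.

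Interferon-stimulated genes of neutrophil-like, monocyte-like and macrophage-like cells had medians below 0 in the 10% Tet2-/- BMT library, whose typed cells mostly carry Xist while those of the other library carry Y-linked transcripts. With Y-carrying cells of both libraries, the median was still -0.60 (-0.71 to -0.45) in neutrophil-like and -1.01 (-1.11 to -0.91) in macrophage-like cells. The 24 such monocyte-like cells of the 10% Tet2-/- BMT library gave -0.07 (-0.31 to 0.04) and are too few to decide. Y-carrying cells of the 2 libraries were unlike in kind. Tissue-aged and activated genes had a median of 0.93 between them in neutrophil-like cells, and tissue-resident genes 0.52 in macrophage-like cells. The comparison therefore cannot separate sex of the cells from their origin or state. The size of the drop differed between kinds of cell, as with Xist-carrying over Y-carrying cells it was -0.91 in neutrophil-like and -0.38 in macrophage-like cells, and within the 10% Tet2-/- BMT library Xist-carrying over Y-carrying cells lay at 0.62 in macrophage-like but at -0.28 in neutrophil-like and -0.18 in monocyte-like cells. Free RNA and scaling by a few abundant genes are argued against in neutrophil-like cells, as the median was -0.76 with free RNA from barcodes with 51 to 200 UMIs subtracted and -0.61 with TMM. The Tet2 genotype of the transplanted cells may be the cause, but with 1 library per group it cannot be told apart from other differences. These include differences between animals, libraries, sex of the cells, the mix of clusters or, if they differed, sort gates. Y-carrying cells of the 10% Tet2-/- BMT library, if they came from the recipient, would not carry the genotype of the transplant.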
